A study of Mus musculus with 10 samples.

How the data were processed

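Chromatin accessibility was measured by ATAC-seq on nuclei cut out of tissue sections with a laser (laser-capture microdissection, LCM). In ATAC-seq the transposase Tn5 cuts open chromatin and inserts sequencing adapters there, so that read density reports accessibility. Per the labels' protocols, fresh frozen lung and brain sections of wild-type C57BL/6J mice, a standard inbred laboratory strain, were treated with Tn5 on the slide for 1 h at 37 °C before any nucleus was cut out. A mini-bulk, the material of 1 library, then pooled either 50 nuclei captured individually or 10 captured areas of about 20 nuclei each, about 200 nuclei in all. The nuclei were picked at random, crosslinks were reversed for 1 h at 65 °C, and the amplified fragments were read as 50 bp paired ends. There were 3 libraries of each size from lung and 2 of each size from brain, 10 in total.

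The authors deposited 1 table of whole-number read counts, with 37513 peaks as rows and the 10 libraries as columns, and all 10 columns were used. Per the submitters' processing notes, the genome build was mm10 and the tools were bcl2fastq 2.20, Trimmomatic 0.36, Bowtie2 2.4.5, Picard, deepTools 3.1.3, SAMtools 1.14, MACS2 2.2.7.1 and R 4.1.0, with no role or order given. How the peaks of the libraries were merged, which program counted reads, whether a count is a read or a fragment, whether duplicates were removed and whether reads were shifted for the Tn5 offset are not given in the sources used here. The deposited counts were not normalized, as their totals per library ranged from 573596 to 10973796. If PCR duplicates are still in the counts, repeated reads of 1 fragment raise the spread between libraries made from few nuclei. Peaks called mostly from the deeper libraries would favour the tissue of those libraries, and this could not be examined in a merged table.

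The 37511 nuclear peaks had a median width of 164 bp, and 2 wide peaks lay on the mitochondrial genome. Peaks were placed on RefSeq gene models of GRCm38.p6, the same assembly as mm10, from a table that gives gene starts and ends but neither strand nor exons. Transcription start sites, exons, introns and UTRs were therefore not used here. Only protein-coding genes and the genes of the lists below were used to class and assign peaks. In place of promoters, a peak whose centre lay within 1000 bp of either end of a gene was classed as a gene-end peak. Other peaks were gene-body peaks if they overlapped the gene they were assigned to, and otherwise peaks away from gene ends. A peak was assigned to the gene it overlapped or that had an end within 5000 bp, the nearest gene end deciding between several. This gave 28753 peaks an assigned gene, over 12671 genes, and 5775 peaks had more than 1 gene in reach.

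Differential accessibility was tested with edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3, with TMM normalization, on the 37466 peaks with at least 10 reads summed over the 10 libraries. A single model held a mean for each of the 4 tissue-by-size groups, and all groups shared the estimate of the spread. The common dispersion was 0.350, a biological coefficient of variation of 0.591. Brain was compared with lung averaged over both sizes and at each size, 200 nuclei with 50 nuclei in each tissue and averaged over tissues, and the dependence of the tissue difference on size was tested as an interaction. Calls used Benjamini-Hochberg adjusted p-values at 0.05. Levels are printed as reads per 1000000 reads in nuclear peaks (RPM), so that the mitochondrial share does not enter them. Fold changes are the model's log2 values with standard errors (SE). They average the log2 folds at both sizes, so at a peak with 0 reads in a whole group the fold depends on the small prior count of the fit. Values per library, such as read totals and the share of peaks with at least 1 read, were compared with exact permutation tests, two-sided, permuting size within tissue (120 arrangements, smallest p 0.0167) or tissue within size (100 arrangements, smallest p 0.01), with Benjamini-Hochberg adjustment over 25 such tests. For a difference of size effects between tissues, size was also permuted within tissue, which is exact only if size has no effect in either tissue. The share of peaks with a read was computed over nuclear peaks, also after random thinning of every library to 319307 nuclear reads, the smallest nuclear total. Correlations between libraries used log2(CPM + 1) over nuclear peaks.

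A total of 20 gene lists (277 genes) marking lung, vascular, neuronal and glial cell types, Hox genes, synapse genes and housekeeping genes were fixed before the data were examined, together with the model, the alternatives and the rule for naming peaks. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry as checks. Camera asks whether a list differs from the other peaks, and fry whether it differs from no change. The rule named the 8 peaks with the lowest p in each direction that had an assigned gene, 1 per gene, and the 2 peaks with the lowest p in each list, called or not. Some peaks that the rule names are not reported here. Peaks named outside this rule are said to have been chosen after their values were seen. A search for 20 transcription factor motifs and corrections for GC content were planned, but both need genome sequence, which was not used here.

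Scripts were tested on simulated counts for the 37466 peaks with the means and depths of these libraries. The spread of a peak was the same in every simulated library. For the brain-lung comparison, 30% of peaks changed 4-fold and 60% of those changed 16-fold were recovered, and 81.5% and 100% of those in the 25% of peaks with the most reads. For the comparison of sizes in lung, recovery was 22% at 4-fold and 57% at 16-fold, and 71.4% and 89.5% in the 25% of peaks with the most reads. Unchanged peaks made up 4 of 94 and 5 of 84 calls. Depth therefore limits what could be found at peaks with few reads, with 319307 to 465489 nuclear reads in the brain libraries and 340697 to 3075377 in the lung libraries. A level of 0 allows up to 3 reads per library, which is 0.975 RPM in the deepest and 9.40 RPM in the shallowest library. Intervals for shares are 95% Wilson intervals, and these and the floors cover counting error only, since reads carried no molecular identifiers.

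The labels call the replicates technical and do not tie a library to an animal, so libraries of a group may share an animal. All p-values measure the spread between these libraries and are too small as statements about animals if they do. Alternatives tried were other scalings (DESeq2 size factors, library totals, loess offsets), other filters on low counts, DESeq2 1.42.0, limma voom, thinning, a replicate block, fits of fewer samples, and leaving out each library in turn. Fits without the mitochondrial peaks, with nuclear totals, with nuclear reads thinned, and without the 2 lung libraries of 50 nuclei that had the most empty peaks were added after the data were seen. Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3 was used for the remaining computations.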

Results

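Open chromatin was profiled in nuclei captured by laser from mouse lung and brain sections, in mini-bulks of 50 individually captured nuclei or of about 200 nuclei taken as 10 small areas. The 4 groups were lung at 50 nuclei (n = 3), lung at 200 nuclei (n = 3), brain at 50 nuclei (n = 2) and brain at 200 nuclei (n = 2). The design asks whether so few nuclei distinguish the tissues, and whether the size of the capture matters. The number of nuclei and the mode of capture, single nuclei or areas, changed together. Differences between mini-bulk sizes therefore cannot be assigned to either alone. Total reads in peaks were 1675105, 573596 and 1081930 in the lung libraries of 50 nuclei and 2928618, 1896166 and 4083252 in those of 200 nuclei. In brain they were 5519395 and 6603983 at 50 nuclei, and 6904574 and 10973796 at 200 nuclei.

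Most reads of the brain libraries came from mitochondrial DNA, which has no nucleosomes and is readily cut by Tn5. The mitochondrial share of reads in peaks was 94.3% ± 1.26 (SD, n = 2) in brain at 50 nuclei and 94.99% ± 1.08 (SD, n = 2) at 200 nuclei. In lung it was 49.3% ± 8.70 (SD, n = 3) at 50 nuclei and 30.3% ± 7.15 (SD, n = 3) at 200 nuclei. Within size, brain exceeded lung by 54.8 percentage points, and all 4 brain libraries lay above all 6 lung libraries (exact permutation test, two-sided, p = 0.01, the smallest of 100 arrangements; 0.0833 adjusted over 25 tests). What remained for nuclear chromatin was 342368 ± 32612 reads (SD, n = 2) in brain at 50 nuclei and 432150 ± 47148 (SD, n = 2) at 200 nuclei. Lung gave 530614 ± 181937 nuclear reads (SD, n = 3) at 50 nuclei and 2082050 ± 887749 (SD, n = 3) at 200 nuclei.

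**Figure D1:**
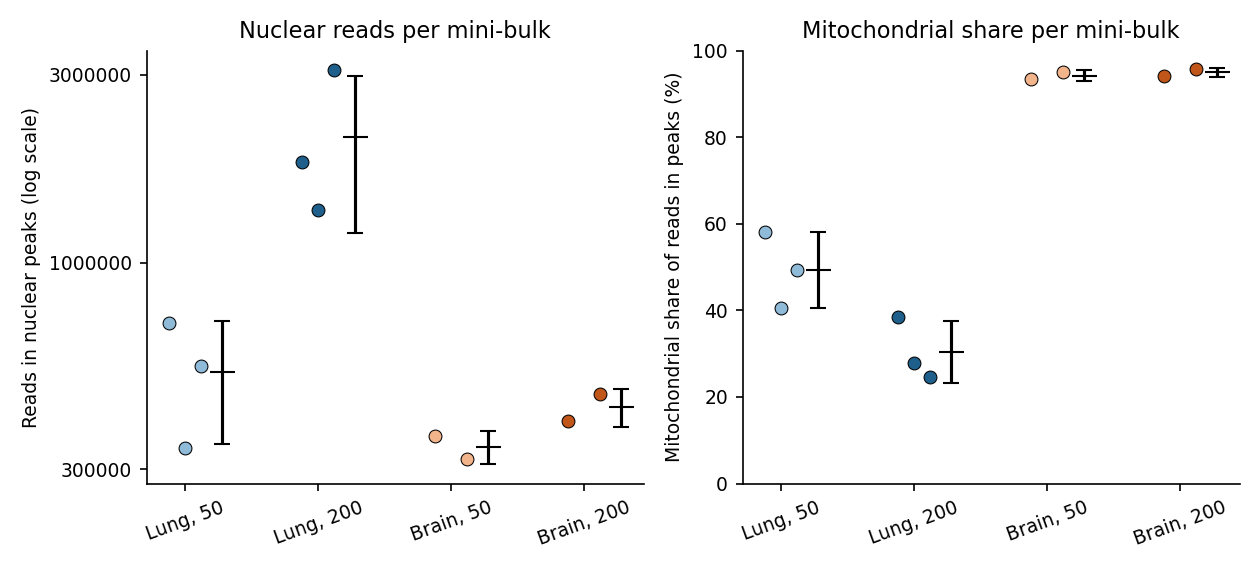
Reads in nuclear peaks (left, log scale) and the mitochondrial share of all reads in peaks (right, percent) for each mini-bulk; points are libraries, bars the mean and SD of a group. Brain libraries lie between 93.4% and 95.8% mitochondrial reads, lung libraries between 24.7% and 58.0%.

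Larger mini-bulks held more reads on average. Total reads in peaks were 2.01-fold higher at 200 than at 50 nuclei within tissue, on the log2 scale a difference of 1.01 (exact permutation test, two-sided, p = 0.0167, the smallest of 120 arrangements; 0.0833 adjusted over 25 tests). Nuclear reads were 2.21-fold higher (exact permutation p = 0.0167; 0.0833 adjusted). In lung alone the nuclear reads were 3.87-fold higher and in brain alone 1.26-fold higher; the exact tests within 1 tissue cannot go below p = 0.1 in lung and 0.333 in brain, and both gave that smallest value. The difference between these effects missed the threshold (exact permutation p = 0.117). Leaving out lung 50-nuclei replicate 2, lung 200-nuclei replicate 1 or 3, or either brain 50-nuclei library raised p for total reads in peaks by mini-bulk size to 0.05, with log2 differences of 0.80, 0.99, 0.87, 0.94 and 1.07.

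The peaks reached by a mini-bulk differed most among the lung libraries of 50 nuclei. Of the 37511 nuclear peaks, 90.9%, 60.9% and 56.1% held at least 1 read in lung 50-nuclei replicates 1, 2 and 3. The share was 96.9% ± 0.755 (SD, n = 3) in lung at 200 nuclei, 92.2% ± 3.02 (SD, n = 2) in brain at 50 nuclei and 89.3% ± 4.48 (SD, n = 2) in brain at 200 nuclei. Averaged over tissues, 200 nuclei exceeded 50 nuclei by 12.4 percentage points, which was within the spread between libraries (exact permutation p = 0.2). With every library thinned to 319307 nuclear reads, lung 50-nuclei replicates 2 and 3 still reached 60.6% and 54.7%, and the other 8 libraries 83.8% to 92.9%.

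**Figure D2:**
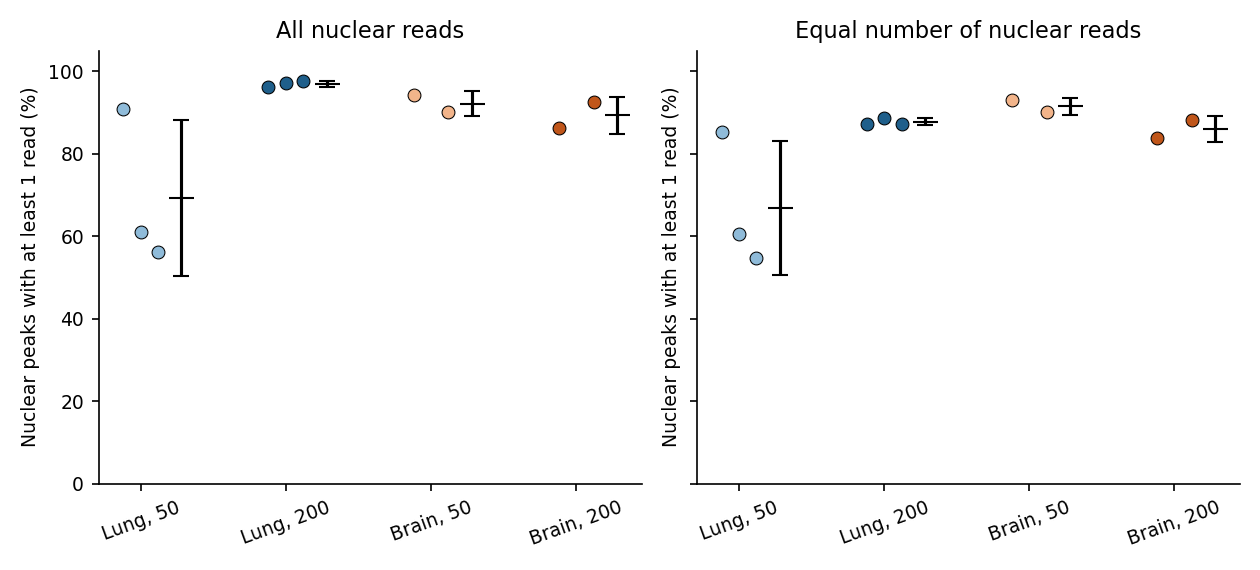
Percent of the 37511 nuclear peaks with at least 1 read in each mini-bulk, with all nuclear reads (left) and after thinning to 319307 nuclear reads (right); points are libraries, bars the mean and SD of a group. Lung 50-nuclei replicates 2 and 3 stay at 60.6% and 54.7% after thinning.

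On average, libraries of a tissue resembled each other more than libraries of different tissues, although the lung libraries at 50 nuclei did so least, with r = 0.467 for replicates 2 and 3. Across nuclear peaks, Pearson's r of log2 CPM had a median of 0.832 (Spearman's rho 0.825) over the 3 pairs of lung libraries at 200 nuclei and 0.562 (rho 0.577) over the 3 pairs at 50 nuclei. The single pairs of brain libraries gave r = 0.687 (rho 0.717) at 50 nuclei and 0.716 (rho 0.739) at 200 nuclei. Libraries of the same tissue but another size had a median r of 0.669 over 13 pairs, and libraries of different tissues 0.487 over 24 pairs (0.395 to 0.564). The mean r within a tissue exceeded that between tissues by 0.204 (exact permutation test of tissue labels within size, p = 0.01, the smallest of 100 arrangements). Depth differed between the groups, so r was also taken with nuclear reads thinned to the smallest nuclear total. Lung at 200 nuclei then had a median r of 0.700, close to brain at 50 nuclei (0.675) and at 200 nuclei (0.682). Lung at 50 nuclei stayed lowest of the groups, at 0.539, and pairs of different tissues had a median of 0.453. The mean difference between these kinds of pairs, within and between tissues, was 0.180 (same exact permutation test, p = 0.01). Peaks are not independent replicates, so no p-value is attached to single correlations.

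Between brain and lung, chromatin was more open in brain at genes of neurons, synapses and oligodendrocytes, and more open in lung at genes of endothelium, alveolar type 1 cells and lung mesenchyme and at Hox genes. Of these 9 lists called by camera, 4 stayed under an adjusted p of 0.05 with an estimated correlation (all neurons, endothelium, alveolar type 1 cells and Hox genes), while synapses went to adjusted p = 0.117, oligodendrocytes to 0.135, lung mesenchyme to 0.187, excitatory neurons to 0.0822 and inhibitory neurons to 0.187. Of 37466 peaks tested, 3803 differed (edgeR quasi-likelihood test, adjusted p at 0.05), with 2158 higher in brain, 2 of them mitochondrial, and 1645 higher in lung. The nuclear peaks higher in brain were narrow, with a median width of 130 bp and a median absolute log2 fold of 4.08. Those higher in lung had a median width of 312 bp and a median absolute log2 fold of 2.36. Read levels differed as well, with a median log2 CPM of 1.43 in the peaks higher in brain and 3.07 in those higher in lung. At peaks with few reads only large folds can be called, so these median folds are not compared at like read levels. Uncalled nuclear peaks had a median width of 160 bp, log2 CPM of 1.75 and absolute log2 fold of 0.80. At an unadjusted p under 0.05 there were 9410 peaks. Nuclei were picked at random and pooled, so these are differences between tissues, and accessibility within a cell type was not measured.

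The count depended on single libraries. It was 7023 without lung 50-nuclei replicate 1, 6553 without replicate 3 of that group, 2252 and 2046 without lung 200-nuclei replicates 2 and 3, 1783 and 1616 without brain 50-nuclei replicates 1 and 2, and 1585 and 1989 without brain 200-nuclei replicates 1 and 2. Without both lung 50-nuclei replicates 2 and 3, an alternative added after the data were seen, it was 8364, 3681 of them shared with the 3803. Scaling by library totals, which counts the mitochondrial reads, called 252 peaks higher in brain and 30079 higher in lung and moved the median log2 fold of all peaks from 0.07 to -3.34. More peaks were higher in lung than in brain also with the default filter of edgeR (1205 against 828), with loess offsets (2355 against 1452), with all reads thinned (1210 against 43) and without both lung libraries (4637 against 3727).

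Neuronal genes stood out in brain. Of 33 tested peaks at 18 genes marking all neurons, 14 were higher in brain and none in lung, and 16 adjusted over the list alone (camera adjusted p = 5.57e-09; adjusted p = 0.0496 with an estimated correlation). Among them, Syt1, a calcium sensor of synaptic vesicle release, had a peak at chromosome 10:109010897-109011154 (mm10), 45 bp from a gene end, with 57.1 ± 15.8 RPM (SD, n = 4) in brain and 2.01 ± 2.09 RPM (SD, n = 6) in lung. Its log2 fold was 5.09 ± 0.74 (SE, adjusted p = 1.42e-05). At Elavl3, which encodes a neuronal RNA-binding protein, the peak at 9:22051927-22052017 held 43 reads in brain and 0 in lung, at least 72.5-fold higher with 3 reads over the lung group as the floor. Other genes with a call included Elavl4, Map2, Meg3, Rbfox1, Rbfox3, Snap25, Thy1 and Tubb3.

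Synapse genes followed, with 7 of 24 peaks higher in brain and 1 higher in lung, or 12 and 2 adjusted over the list alone (camera adjusted p = 5.33e-05; adjusted p = 0.117 with an estimated correlation). Grin1, a subunit of the NMDA receptor, had 37.9 ± 9.77 RPM (SD, n = 4) in brain and 1.04 ± 1.76 RPM (SD, n = 6) in lung at 2:25319058-25319193 (log2 fold 6.08 ± 1.09, SE). Pclo, a scaffold of the presynaptic zone, had 69.9 ± 8.94 RPM in brain and 9.71 ± 6.06 RPM in lung at 5:14514685-14515268 (log2 fold 3.08 ± 0.53, SE), a direction that turned to -0.37 under scaling by library totals. The peak higher in lung belonged to Shank3, which encodes a postsynaptic scaffold.

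Markers of single neuronal classes rested on few peaks. For excitatory neurons 2 of 6 peaks were higher in brain (camera adjusted p = 0.00694; adjusted p = 0.0822 with an estimated correlation), at Camk2a, a kinase of forebrain synapses (18:60925468-60925607, log2 fold 6.45 ± 1.00, SE), and at Neurod6 (6:55676927-55677033, 4.27 ± 1.29). For inhibitory neurons 2 of 3 were higher in brain (camera adjusted p = 0.00694; adjusted p = 0.187 with an estimated correlation). Among them was Dlx6, a homeobox factor of inhibitory neurons (6:6862785-6862885, log2 fold 5.18 ± 1.33, SE). The list of forebrain regulators missed the threshold as a whole with camera (adjusted p = 0.112) and passed it with fry (adjusted p = 0.0109).

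Among glial genes, those of oligodendrocytes had 4 of 16 peaks higher in brain, at Cnp, Mag, Mbp and Olig1 (camera adjusted p = 0.0129; adjusted p = 0.135 with an estimated correlation). Olig1, a regulator of the oligodendrocyte lineage, had 54.4 ± 16.2 RPM (SD, n = 4) in brain and 1.09 ± 2.22 RPM (SD, n = 6) in lung at 16:91269572-91269786. Mag, a myelin protein, had a log2 fold of 6.71 ± 1.19 (SE) at 7:30914814-30914952. The astrocyte list was not called (1 of 11 peaks, Sox9; camera adjusted p = 0.511), nor was the microglia list (1 of 6, Sall1; 0.340), the cerebellum list (1 of 2, Cbln1; 0.448) or the list for choroid plexus and ependyma (0.713), in which 1 of 7 peaks, at Aqp1, was higher in lung. With fry, the microglia (adjusted p = 0.0137) and cerebellum (adjusted p = 0.0375) lists passed, both higher in brain.

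Endothelial genes were the list with the lowest p in lung. Of 68 tested peaks at 17 genes, 25 were higher in lung and none in brain, or 32 and 1 adjusted over the list alone (camera adjusted p = 1.11e-14; adjusted p = 0.0496 with an estimated correlation). The 13 genes were Car4, Cdh5, Cldn5, Egfl7, Eng, Erg, Esam, Kdr, Pecam1, Robo4, Sox18, Tek and Tie1. Eng, a TGF-beta co-receptor of endothelium, had 148 ± 31.8 RPM (SD, n = 6) in lung and 24.6 ± 8.65 RPM (SD, n = 4) in brain at 2:32661489-32662138, within the gene (log2 fold -2.57 ± 0.33, SE, adjusted p = 3.19e-06). Erg, an endothelial transcription factor, had 99.0 ± 24.7 RPM in lung and 18.9 ± 13.1 RPM in brain at 16:95438902-95439496 (log2 fold -2.57 ± 0.40, SE).

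Alveolar type 1 cells, the thin cells of gas exchange, had 6 of 37 peaks higher in lung and none in brain, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00202; adjusted p = 0.0496 with an estimated correlation). With its 14 gene-end peaks only, the list was not called (adjusted p = 0.293). The 6 peaks lay at Clic5 (17:44230121-44230521, log2 fold -2.92 ± 0.53, SE) and Gprc5a (6:135065389-135065745, -2.19 ± 0.47). Lung mesenchyme genes had 5 of 21 peaks higher in lung, at Foxf1, Tbx2 and Tbx3, and 1 higher in brain, at Wnt2 (camera adjusted p = 0.00694; adjusted p = 0.187 with an estimated correlation). Tbx3, a T-box transcription factor, had 203 ± 45.0 RPM (SD, n = 6) in lung and 45.2 ± 11.5 RPM (SD, n = 4) in brain at 5:119670363-119671082. Foxf1, a regulator of lung mesenchyme, had a log2 fold of -3.46 ± 0.68 (SE) at 8:121083104-121083332. Hox genes, which are not expressed in forebrain, had 3 of 15 peaks higher in lung, at Hoxa3 and Hoxa5, or 6 adjusted over the list alone (camera adjusted p = 2.30e-05; adjusted p = 0.0496 with an estimated correlation). The Hoxa5 peak at 6:52204376-52204673 had 63.2 ± 9.04 RPM in lung and 3.91 ± 3.39 RPM in brain.

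Other lung and general lists were not called by camera. Alveolar type 2 genes had 1 of 22 peaks called, higher in brain at Etv5 (16:22428972-22429286, log2 fold 1.91 ± 0.46, SE), which turned to -1.60 under library totals (camera adjusted p = 0.511). Airway genes had 1 of 10, higher in brain at Sox2, a factor of airway epithelium and of neural progenitors (3:34649845-34650018, 6.64 ± 1.16; 0.713 for the list). No peak was called for immune (20 peaks, 0.538), erythroid (3 peaks, 0.713) or smooth muscle genes (7 peaks, 0.634). Housekeeping genes had 1 of 40 called, higher in lung at B2m, a component of MHC class I (2:122147449-122147817, -1.21 ± 0.32), and the list was not called (0.713). Its median log2 fold was 0.13 and its mean 0.16, while camera placed it lower in brain. Smooth muscle genes had a median of -0.01 and a mean of 0.43, and fry called the list higher in brain (adjusted p = 0.0310).

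**Figure D3:**
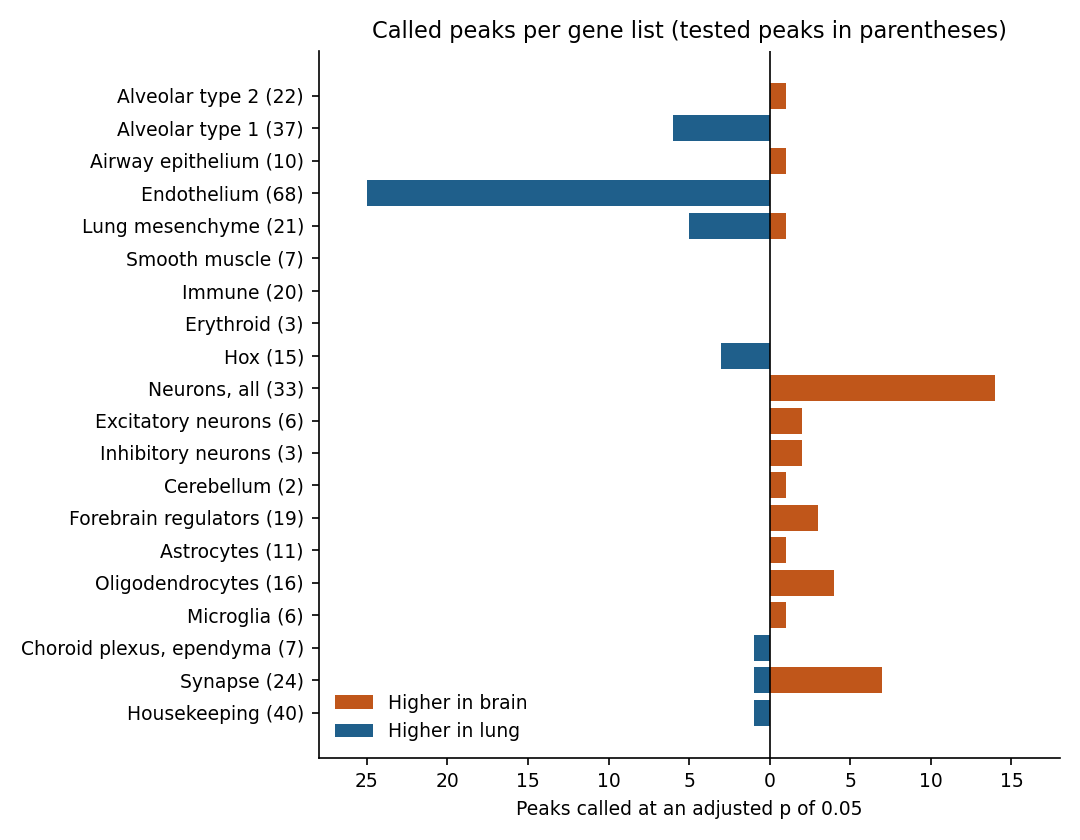
Number of peaks called higher in brain (right) and higher in lung (left) for each of the 20 gene lists, with the number of tested peaks in parentheses. Endothelium has 25 of 68 peaks higher in lung, and the list for all neurons 14 of 33 higher in brain.

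Among the 8 peaks with the lowest p in brain, Kcnj10, a potassium channel of astrocytes and oligodendrocytes, had 95.5 ± 17.7 RPM (SD, n = 4) in brain and 0.952 ± 1.09 RPM (SD, n = 6) in lung at 1:172349929-172350283, within the gene (log2 fold 7.48 ± 0.67, SE, adjusted p = 2.62e-09). Clstn3, a synaptic adhesion protein, had a log2 fold of 6.90 ± 0.74 at 6:124464666-124464981. Pou3f3, a neural transcription factor, had 5.78 ± 0.65 at 1:42695626-42695875, and Slc38a3, a glutamine transporter, 7.52 ± 0.88 at 9:107659653-107659896. At Eml2 (7:19176266-19176396) brain held 94 reads and lung 0, at least 158.5-fold higher with 3 reads over the lung group as the floor. The other 3 were Cmtm5 (14:54935928-54936171, 6.42 ± 0.72), Ttyh1 (7:4123792-4124029, 5.30 ± 0.62) and Dctn1 (6:83185981-83186173, 6.64 ± 0.77).

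In lung, the peaks with the lowest p included Klf2, a flow-responsive endothelial factor, with 276 ± 51.2 RPM (SD, n = 6) in lung and 67.0 ± 7.21 RPM (SD, n = 4) in brain at 8:72318747-72319354 (log2 fold -2.01 ± 0.25, SE, adjusted p = 1.08e-06). Sema3g, a semaphorin of vessels, had -3.12 ± 0.36 at 14:31232996-31233469, and Lmna, which encodes lamins A and C of the nuclear envelope, -2.18 ± 0.28 at 3:88509880-88510413. Among peaks with an assigned gene, the lowest p belonged to one in Anks1 (17:28015081-28015765) with 210 ± 39.5 RPM in lung and 23.7 ± 5.37 RPM in brain. The others were Tmcc3 (10:94462464-94463125, -3.36 ± 0.37), Cttnbp2nl (3:105054883-105055442, -2.63 ± 0.32), Pakap (4:57679037-57679636, -3.58 ± 0.45) and Ehd1 (19:6300161-6300765, -2.55 ± 0.33).

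**Figure D4:**
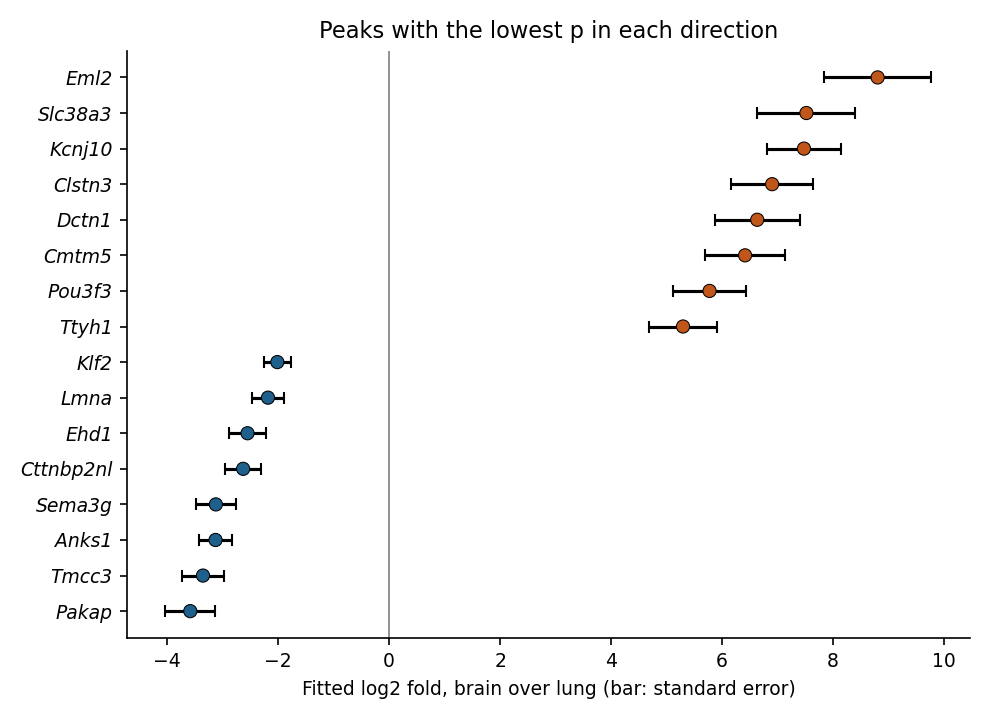
Fitted log2 fold of brain over lung with its standard error (bars) for the 8 peaks of lowest p in each direction. Values run from -3.58 at Pakap to 8.81 at Eml2, which had 0 lung reads and whose value depends on the prior count of the fit; the next highest is 7.52 at Slc38a3.

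Some of these calls were fragile. Peaks that the filter of a setting removed were not tested there and are not counted as ended below. The default filter of edgeR left only 37 of the 50 named called peaks to be tested. Other settings with all 10 libraries ended the call at Cbln1 and Neurod6 in 4 cases each. At Aqp1, B2m and Sox9 they did so in 2 cases each. At Dlx6, Etv5, Foxf1, Gprc5a, Pclo, Pou3f3, Syt1 and Ttyh1 they did so in 1 case, which was limma voom for Gprc5a. Leaving out 1 library at a time ended the call at Cbln1 in 7 of 10 cases, at Neurod6 in 6, at Aqp1 in 4 and at Dlx6, Hoxa3 and B2m in 2 each.

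Peaks higher in lung lay away from gene ends more often than those higher in brain. Gene-end peaks, within 1000 bp of either end of a gene, made up 39.6% of the peaks higher in brain (853 of 2156, 95% Wilson interval 37.5 to 41.6), 13.7% of those higher in lung (225 of 1645, 12.1 to 15.4) and 36.8% of all tested nuclear peaks. The odds ratio between the directions was 4.13 (Fisher's exact test on peaks, p = 1.26e-72, as a description, since peaks are not replicates). Peaks away from gene ends, which did not overlap an assigned gene and were not near a gene end, made up 24.8% in brain and 43.8% in lung. For the genomic class of called peaks, the odds ratio of gene-end peaks was 2.57 without brain 200-nuclei replicate 2, 8.39 with the default filter of edgeR and 6.23 with limma voom. It turned to 0.527 with library totals as the scaling and to 0.738 after thinning all reads, mitochondrial ones included.

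The tissues were also compared at each mini-bulk size, with the spread estimated from all 10 libraries. At 50 nuclei 527 peaks differed, 344 higher in brain and 183 higher in lung, and at 200 nuclei 839 differed, 375 higher in brain and 464 higher in lung (edgeR, adjusted p at 0.05). The nuclear lists shared 126 peaks higher in brain and 129 higher in lung, against 3.41 and 2.27 for independent lists, and no peak was called in opposite directions. Of 525 nuclear peaks called at 50 nuclei, 522 had the same sign at 200, and of 837 called at 200 nuclei, 834 had the same sign at 50. The 2 comparisons share no library, but they share the spread fitted for each peak, and libraries of a tissue may share an animal. The values for independent lists take each peak as equally likely to be called, so part of the overlap above them was built in. Across all peaks the log2 folds at 50 and at 200 nuclei correlated at r = 0.525.

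Which tissue had more of the calls was not stable at either size. At 200 nuclei brain had more with DESeq2 size factors (471 against 389), DESeq2 (825 against 586), limma voom (859 against 659), loess offsets (346 against 335), nuclear totals (459 against 427), and without lung 50-nuclei replicate 1 (513 against 353) or brain 200-nuclei replicate 1 (10 against 5). At 50 nuclei lung had more with library totals (19678 against 72), all reads thinned (60 against 5), loess offsets (191 against 82), without lung 50-nuclei replicates 2 and 3 (842 against 689), and without brain 200-nuclei replicate 1 (100 against 74) or 2 (108 against 93). Both counts moved with the libraries in the model. With only the 5 libraries of a size they were 9 at 50 nuclei and 5653 at 200 nuclei. At 50 nuclei the count was 2884 and 1195 without lung 50-nuclei replicates 1 and 3, 319, 249 and 290 without lung 200-nuclei replicates 1, 2 and 3, 23 and 14 without brain 50-nuclei replicates 1 and 2, and 174 and 201 without brain 200-nuclei replicates 1 and 2. At 200 nuclei it was 1544 and 2763 without lung 50-nuclei replicates 2 and 3, 312, 194 and 161 without lung 200-nuclei replicates 1, 2 and 3, 547 without brain 50-nuclei replicate 1, and 15 and 76 without brain 200-nuclei replicates 1 and 2.

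No peak differed in accessibility between mini-bulk sizes at an adjusted p of 0.05. In edgeR the counts were 0 for lung (3071 at an unadjusted p under 0.05), 0 for brain (426) and 0 averaged over both tissues (1375). DESeq2 called 2, 0 and 0 peaks, and limma voom 538, 0 and 0. With no change at all, a 0.05 share of the 37466 peaks would have an unadjusted p under 0.05. The edgeR counts in brain and over both tissues were below that share, so those tests were conservative. Recovery was not simulated for them, and their 0 calls are weak evidence against an effect of size. In the simulated comparison of sizes in lung, 22% of peaks changed 4-fold and 57% of those changed 16-fold were recovered, and 71.4% and 89.5% in the 25% of peaks with the most reads. All simulated libraries had the same spread per peak, without the many empty peaks of lung 50-nuclei replicates 2 and 3. Recovery in the real libraries may therefore be lower. In lung the 2 mitochondrial peaks came closest, lower at 200 nuclei by -0.99 and -1.01 on the log2 scale (adjusted p = 0.0567 for both). Leaving out lung 50-nuclei replicate 1 gave 252 peaks, 243 of them higher at 200 nuclei, leaving out replicates 2 and 3 gave 2 and 6, and leaving out lung 200-nuclei replicate 1 gave 2.

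In the main fit, the dependence of the tissue difference on mini-bulk size passed the threshold for no single peak. The interaction called 0 peaks in edgeR, with 1554 at an unadjusted p under 0.05, and 0 in both DESeq2 and limma voom. It called 2 peaks each with DESeq2 size factors in edgeR, with library totals and with the replicate block. The 1554 were below a 0.05 share of the 37466 peaks, and recovery was not simulated, so this test was conservative as well.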

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

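The tests of explanations in this part were chosen only after the results were seen.

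A signal outside the comparisons was that the 2 Y-linked peaks, at Eif2s3y (Y:1010229-1010390) and Uty (Y:1245744-1245834), held 62 reads in brain and 0 in lung, at least 104.6-fold higher in brain with 3 reads over the lung group as the floor (exact permutation test of tissue within size, p = 0.01, the smallest it can give). Lower depth does not account for this, since 313.7 reads were expected in lung at the brain rate, nor does a mislabelled library, as the lowest brain library held 12 Y reads and every lung library 0. A candidate explanation is that the lung came from female and the brain from male animals, a hypothesis that also needs more reads in lung at Xist, which is expressed from the inactive X chromosome of females. RPM in the 2 peaks of Xist was 3.34-fold higher in lung (95% counting interval 1.92 to 6.38; exact permutation p = 0.02), although lung 50-nuclei replicate 3, at 9.13 RPM, lay within the brain libraries. The labels give no sex and tie no library to an animal. If lung was female and brain male, the tissues came from different animals. Sex and animal would then be confounded with tissue at every peak, not only at those on X and Y.

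The effect of mini-bulk size on the mitochondrial share differed between the tissues by 19.7 percentage points (exact permutation test of the difference, p = 0.0333, 0.104 adjusted over 25 tests), with -19.0 points in lung and 0.719 in brain. The brain share lay near its upper limit, where percentage points have little room to move. As log odds, the size effects were -0.818 in lung and 0.141 in brain. These differed by 0.959 (exact permutation test of the difference, p = 0.05, unadjusted). The high share in brain was not confined to the larger areas, since brain already exceeded lung by 44.9 points among mini-bulks of individually captured nuclei. Both tissues were captured at both sizes, and single captures may also take cytoplasm along. The comparison therefore cannot show whether captured cytoplasm differed between the tissues. A lower nuclear yield in brain stays open: mitochondrial reads were higher in brain by 3.41 on the log2 scale, but total reads were also higher, by 2.10, so that read numbers follow depth. A difference between the tissues in mitochondrial content, and a difference in how their sections or libraries were handled, stay open as well and were not tested.

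The share of peaks with at least 1 read differed between sizes by 27.6 percentage points in lung and by -2.87 in brain, a difference of -30.5 percentage points (exact permutation test of the difference, p = 0.0333, 0.104 adjusted) and of -26.3 points at equal nuclear depth (p = 0.0167, the smallest it can give, 0.0833 adjusted). Lower depth does not account for lung 50-nuclei replicates 2 and 3, which reached at most 60.6% of peaks at equal nuclear depth, against 83.8% or more in the other 8. A candidate explanation is that few starting fragments were read several times each, and at equal depth at most 6.97% of their non-empty peaks held a single read, against 10.8% or more in each of the other 8 libraries. That test does not decide, because fewer non-empty peaks at equal depth leave more reads per peak by themselves. No biological explanation was tested.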

How the results depend on the processing

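Fits without the mitochondrial peaks, with nuclear totals, with thinned nuclear reads and without lung 50-nuclei replicates 2 and 3, size effects on nuclear reads, a block for the gene lists and leaving out libraries for the mitochondrial share were chosen after the data were seen; other alternatives were fixed before. Motif searches, GC offsets and GC offsets with a replicate block were not run, as they need genome sequence. Unless stated, the cause of a change was not tested. The 3803 brain-lung calls (2158 higher in brain, 1645 in lung) became 30331 with library totals (252 and 30079), 2033 with the default filter of edgeR (828 and 1205; fewer peaks tested), 1253 with all reads thinned (43 and 1210; few nuclear brain reads left) and 8364 without both lung libraries (3727 and 4637). The split moved to 3248 and 1019 with limma voom (4267), and to 1452 and 2355 with loess offsets (3807). Library totals reversed 701 of the 3803 calls and thinning all reads 110 of the 2536 still tested; no call reversed under the other alternatives. The median log2 fold of all peaks moved from 0.07 to -3.34 with library totals, -1.59 with all reads thinned, -0.15 with loess offsets, 0.33 with limma voom and 0.20 with nuclear reads thinned.

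At 50 nuclei the 527 calls became 19750 with library totals, 317 with the default filter, 1836 with DESeq2, 1094 with limma voom (1045 higher in brain, 49 in lung, against 344 and 183), 65 with all reads thinned, 273 with loess offsets (82 and 191), 1531 without both lung libraries and 9 with only the 5 libraries. At 200 nuclei the 839 calls became 29400, 414, 1411, 1518 and 116 under the first 5 of these, 429 with nuclear reads thinned, 6213 without both lung libraries and 5653 with only the 5 libraries. For size in lung, 0 became 2 with DESeq2 size factors, with DESeq2 and with all reads thinned, 3 with library totals, 538 with limma voom and 15 without both lung libraries. For size over both tissues, 0 became 2 with library totals and 8 without both lung libraries, and for the interaction 2 with DESeq2 size factors or library totals and 3 without both lung libraries. The size contrast in brain stayed at 0 under each alternative run. Recovery was not simulated for it, and in the main fit only 426 of 37466 peaks had an unadjusted p under 0.05, so its 0 calls are weak evidence.

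Leaving out 1 library at a time, with a lone remaining sample assumed to vary like the other groups, gave 1585 to 7023 brain-lung calls, 14 to 2884 at 50 nuclei, 15 to 2763 at 200 nuclei and 0 to 252 for size in lung. The log2 difference in total reads was 0.80 to 1.19 and lost its side of the threshold in 5 of 10 cases. The difference in the share of peaks with a read (9.06 to 17.8 points), the correlation difference (0.189 to 0.226), the mitochondrial difference (52.6 to 57.0 points) and the number of lists called (9) kept theirs. The odds ratio of gene-end peaks was 2.57 to 5.66, reversed to 0.527 with library totals and 0.738 with all reads thinned.

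With the replicate number as a block, the brain-lung calls became 2042 (970 higher in brain, 1072 in lung) and those at 200 nuclei 532, and size in lung, size over both tissues and the interaction 2 each. Deviations of same-numbered libraries from their group means correlated by at most 0.0195 and at least -0.0297, which gave no sign that the numbers pair the libraries. With few reads per peak, and mirrored deviations in brain groups of 2 libraries, a weak pairing cannot be excluded. The number of lists called, 9, became 4 with an estimated correlation and 8 with gene-end peaks only. With fry, which tests a list against no change and not against the other peaks, it was 13. Those added were forebrain regulators, microglia, smooth muscle and cerebellum. Alveolar type 1 genes lost their call with gene-end peaks only (adjusted p = 0.293). Airway genes, never called, reversed with gene-end peaks only (adjusted p = 0.740), with fry (0.928) and in 2 of 10 fits leaving out 1 library (0.533 to 0.998 over all 10). Housekeeping genes reversed with gene-end peaks only (0.867) and fry (0.796).

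Of 50 called peaks named, 3 reversed with library totals: Etv5 to -1.60, Cbln1 to -0.56 and Pclo to -0.37. Without a reversal, 7 of the 50 lost their call with library totals and 4 with the replicate block. With all reads thinned, 27 kept their call, 7 lost it, and the rest fell below the filter on low counts and were not tested. With the default filter of edgeR, 37 kept their call and the rest were not tested. Loess offsets ended 3 calls, limma voom 3 (Aqp1, B2m and Gprc5a), leaving size out of the model 2 and thinning nuclear reads 1. Among 13 uncalled peaks, library totals gave Lpcat1 -0.36, Foxj1 -2.27, Lmod1 -1.40, Ptprc -0.998, Epor -2.02, Aif1 -2.32 and Lmx1a -0.64; thinning all reads gave Foxj1 -0.0014 and Aif1 -1.08. Etv1, at -0.04, turned to 0.026 with DESeq2 size factors, 0.028 with DESeq2, 0.018 with the default filter, 0.058 with limma voom, 0.014 without mitochondrial peaks, 0.21 with nuclear reads thinned and 0.15 without both lung libraries, and lay between -0.46 and 0.32 leaving out 1 library. Depth limits peaks with few reads, with 319307 to 465489 nuclear reads in the brain libraries and 340697 in the shallowest lung library.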

Other observations

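The tests in this part were chosen only after the main counts were seen. Called peaks were clustered at some loci. Among 4282 windows of 250 kb with at least 3 tested peaks, 7 held more lung-high peaks than the overall rate gives (Benjamini-Hochberg adjusted p at 0.05). Those of lowest p were a window around Tmem100, a gene of lung endothelium, with 9 of 23 peaks (chromosome 11, peaks from 90025982 to 90130464, adjusted p = 0.000858), and one around Smad6, an inhibitor of BMP signalling, with 8 of 18 (chromosome 9, 64021911 to 64094584, adjusted p = 0.000858). In brain 1 window passed, in which all 4 peaks were higher in brain (chromosome 6, 126586022 to 126740714, adjusted p = 0.0468). It holds the potassium channel genes Kcna1, Kcna5 and Kcna6. Neighbouring peaks are not independent, so these p-values are descriptions.

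The lung-high peaks of lowest p without a gene in reach, named after their values were seen, included 8:120876053-120876872 and 8:120830632-120831200. They lie between Irf8 and Foxf1, 119359 and 73938 bp from Irf8, the nearest coding gene, and 207514 and 253186 bp from Foxf1. Lung held 226 ± 68.0 RPM (SD, n = 6) at the former and brain 14.7 ± 9.81 RPM (SD, n = 4), a log2 fold of -3.94 ± 0.38 (SE, edgeR adjusted p = 5.76e-09). At the latter lung held 162 ± 28.8 RPM and brain 15.8 ± 11.5 RPM. A peak at 17:46104349-46105046, 71972 bp from Vegfa and 5958 bp from Mrps18a, had 179 ± 48.5 RPM in lung and 17.98 ± 12.4 RPM in brain. A lung-high window on the X chromosome covers Firre, a long noncoding RNA gene bound by CTCF on the inactive X. In it 8 of 28 peaks were higher in lung (X, 50572756 to 50623370, adjusted p = 0.0180). The 25 peaks of the gene summed to 437 ± 163 RPM (SD, n = 6) in lung and 80.2 ± 14.96 RPM (SD, n = 4) in brain, with 109.5 RPM in lung 50-nuclei replicate 3, the lowest lung library. Over the other 782 X peaks, 24 were higher in lung and 19 in brain.

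A hypothesis was that brain-high peaks lie in longer genes, as neuronal genes are long, both within gene bodies and at gene ends. Brain-high peaks in gene bodies belonged to genes with a median length of 97.6 kb (622 genes), lung-high ones 71.5 kb (484 genes) and all tested ones 53.2 kb. The mean log2 length differed by 0.50 (permutation test over genes, p = 1e-05, the smallest it can give). At gene ends the medians were 34.0 kb, 15.5 kb and 23.7 kb (permutation p = 1e-05). The values are consistent with the hypothesis in both classes, although genes of both directions were longer than tested genes within gene bodies.

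Other splits of the libraries bear on the counts of called peaks. Of 100 splits of the 10 libraries into groups of the same sizes, 1 gave as many peaks as brain against lung, the real one with 3803. The highest other gave 170. Other splits mix the tissues and so raise the fitted spread, which holds their counts down. The real split being highest therefore shows that the libraries group by tissue, but not how many of its calls are free of chance. Chance between animals is not excluded, since the labels tie no library to an animal. For 200 against 50 nuclei averaged over tissues the real count was 0 and the highest other 2, and since each of the 60 splits gives at least 0, their number decides nothing. For size in lung there are 10 splits, too few for a share under 0.05; the real one gave 0 peaks and the highest other 2.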
